A study of Mus musculus with 9 samples.

How the data were processed

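RNA was sequenced from 9 libraries of RAW264.7 cells, a mouse macrophage line treated with lipopolysaccharide (LPS) at 100 ng/ml for 2 h. Per the labels' protocols, 3 libraries came from immunoprecipitates (IPs) made with rabbit polyclonal antibodies to Roquin on protein A/G beads, 3 from control IPs made with beads alone, and 3 from RNA isolated from the lysate before IP (input). The series' design text gives the replicates of each group as biological. The libraries were prepared with the TruSeq RNA kit and sequenced on a HiSeq 2000.

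The authors' deposited table held, per the file headers, the number of reads per gene in each library, and these values were raw counts: whole numbers with totals from 1799390 to 12975767. It also held a ratio of Roquin IP to control IP whose header gives log2. The deposited ratio was on a linear scale, since none was negative and the 5508 finite ratios of 1 or more lay within 0.5% of ratios recomputed from the counts with DESeq-type size factors. The authors' p-value for Roquin IP against control IP stood beside it, and whether it was adjusted is not given in the sources used here. The last column of the deposited table gave the authors' prediction, as a text class, of a constitutive decay element (CDE, a stem-loop bound by Roquin) in each gene. Per the submitters' processing notes, CASAVA 1.8.2, BWA and DESeq 1.8.3 were used, and the genome build, annotation, read filters and strand handling are not given in the sources used here. The table listed 20467 genes by symbol, 6312 of them with no count in any library, and a further 7480 entries without a symbol that were not used. Reads shared by near-identical copies, such as histone and ribosomal protein genes and their pseudogenes, and by overlapping genes cannot be assigned with certainty, so values of such genes are uncertain.

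Library totals were 3547517, 12975767 and 12898468 reads in Roquin IP, 2929537, 4180549 and 8466096 in control IP, and 2122288, 2055795 and 1799390 in the input. Levels are given in CPM (counts per 1e+06 reads) of the library size scaled by its TMM factor, so they differ from shares of all reads. A level of 1 CPM stood for 2.38 to 10.3 counts in Roquin IP, 3.28 to 11.6 in control IP and 2.02 to 2.53 in the input. A count of 0 allowed up to 3 counts, or 0.258 to 1.49 CPM per library. Counting intervals are at the 95% level. Intervals and floors cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. No libraries were duplicates: between replicates of a group the chi-square per degree of freedom was 14.7 to 122.2, and Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.845 to 0.960.

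Counts were fitted with edgeR 4.0.16 (quasi-likelihood F test, glmQLFit with robust estimation off, TMM factors) in R 4.3.3, with all 9 libraries in 1 fit and group as the only term. filterByExpr with a minimum count of 10 left 9567 genes. The common biological coefficient of variation was 0.35, with 8.13 prior and 6 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted in Roquin IP against control IP, Roquin IP against input, and control IP against input. Genes enriched over both backgrounds passed in both Roquin comparisons with at least 2-fold change. Those comparisons share the Roquin IP libraries, and with 3 libraries they cannot be divided into separate sets, so the overlap without any effect was simulated in 20 datasets, which also gave the overlap of the comparisons that share the input libraries.

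Lists of genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the 16 lists with 5 or more measured members. The lists were reported Roquin targets, cytokines and chemokines, NF-kappaB pathway, immediate early genes, MAP kinase feedback, mRNA decay machinery, interferon response, ribosomal proteins, nuclear-encoded oxidative phosphorylation, replication histones, endoplasmic reticulum (ER) folding, lysosome, macrophage identity, cell cycle, housekeeping and translation factors. Lists of mitochondrially encoded RNAs, nuclear noncoding RNAs, lymphocyte markers, and fibroblast, epithelial and endothelial markers had too few measured members to test.

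The stem-loop pattern TTCYRYGAA (Y, pyrimidine; R, purine) was searched in the longest annotated 3' untranslated region (3' UTR) of each gene in the GENCODE annotation of the mouse genome. Of the genes tested, 8772 matched by symbol, 727 by a RefSeq synonym, and 9440 (98.7%) had a 3' UTR. A strict form required 2 further base pairs on the stem. Fisher's exact test (two-sided) compared genes higher in Roquin IP over control IP by at least 2-fold with the other genes. A logistic regression added UTR length and the mean level over all 9 libraries, and patterns with the loop or the stem swapped served as controls. BLAST 2.17.0 (blastn, word size 11) and Python 3.11.15 with matplotlib 3.10.9 served the sequence searches and the plots.

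The groups, tests, lists, patterns and the rule for naming genes were fixed before the data were examined. The rule named the 12 highest and 12 lowest genes in Roquin IP against control IP and the 6 highest and 6 lowest in the other comparisons, among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups. It also named every measured reported target, Rc3h1 and Rc3h2, the 10 genes most enriched over both backgrounds, and up to 4 members of each other list with the smallest adjusted p. Predicted loci could rank but are given at most as a count, and genes with provisional symbols were later treated the same way. Other genes in the text were chosen after their values were seen.

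The replicate numbers come from the labels, which do not say that libraries of 1 number share a culture. Whether they pair the libraries was therefore checked by correlating the residuals from the group means: libraries with the same number had r of 0.152 to 0.58, those with different numbers -0.433 to -0.0185, and 9 of 9 libraries correlated best with their own number. Residuals cancel out within a group, so a positive same-number r forces negative values among different numbers. The 9 matches are therefore not independent of each other. Every same-number r was over 0.1, so the numbers were taken to pair the libraries, and a fit with the number as a block was given beside the results it changed.

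The alternatives were DESeq2 1.42.0, other scalings (RLE, upper quartile and library size alone), no filter and a stricter filter, the replicate block, only the groups compared, leaving out each library, and other forms of the list and stem-loop tests. Leaving out Lars2, thinning to the smallest library, leaving out all libraries numbered 1, taking the calls of other tests for the stem-loops, and covariates for UTR composition, for the level in the input alone and for no level were added after the data were seen.

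The fits were tested on simulated data with 25 genes changed per fold size and direction. In Roquin IP against control IP, 4%, 88%, 100% and 100% of genes raised 2-, 4-, 8- and 16-fold were recovered, and 8%, 72%, 92% and 92% of those lowered. In Roquin IP against input the shares were 20%, 92%, 100% and 100% of raised and 8%, 56%, 76% and 84% of lowered genes. In control IP against input they were 16%, 92%, 100% and 100% of raised and 12%, 76%, 88% and 100% of lowered genes. False calls were 10 of 149, 9 of 143 and 11 of 157. With nothing changed, 10 datasets gave 4 calls in all and 0 lists past the threshold. Genes were drawn independently of each other in the simulated data, so the 0 lists cannot show how camera behaves with correlated genes. In the real libraries the estimated correlation within a list reached 0.694 (replication histones). A list of 28 genes raised 4-fold reached an adjusted p of 1.37e-50, and stem-loop genes raised 16-fold gave an odds ratio of 71.6. A 2-fold change was thus mostly not detectable with 3 libraries per group.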

Results

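RNA recovered with the Roquin antibodies was compared with RNA held by beads alone and with RNA of the lysate in LPS-treated RAW264.7 macrophages. The control IPs held no antibody, so RNA bound through other proteins that the antibodies may hold cannot be told from RNA bound to Roquin. Roquin proteins, encoded by the paralogs Rc3h1 and Rc3h2, bind stem-loops in mRNAs and direct them to decay. Tnf, which encodes a main inflammatory cytokine of macrophages, held 21.9% ± 4.91 (SD, n = 3) of all reads in Roquin IP, against 0.207% ± 0.0598 in control IP and 0.310% ± 0.178 in the input. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, held 18.3% ± 4.93 of the reads in Roquin IP, 35.2% ± 6.48 in control IP and 37.5% ± 4.49 in the input (SD, n = 3 each). The totals ranged from 1799390 to 12975767 reads per library.

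The comparison of Roquin IP with control IP asked which mRNAs the antibodies brought down beyond those held by beads alone. Nfkbid, which encodes a nuclear inhibitor of NF-kappaB, was 469-fold higher in Roquin IP and had the largest change among the genes named by rule. Tnf was 190-fold higher. The mRNAs of both Roquin genes were themselves enriched: Rc3h1 was 98.8-fold and Rc3h2 43.7-fold higher. Also near the top were Irf4, a transcription factor, Socs1, an inhibitor of cytokine receptor signalling, and the secreted factors Ccl4 and Csf3.

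In total 360 of 9567 genes were higher in Roquin IP than in control IP, with a median of 5.16-fold, and 114 of them were more than 8-fold higher. edgeR called 0 genes lower, while 204 were lower and 759 higher at an unadjusted p under 0.05. DESeq2 called 471 higher and 5 lower, and the fit with the replicate block 528 higher and 11 lower. After a correction for GC content and transcript length 316 were higher and 5 lower, and with the block as well 442 and 112. Scaling by library size alone gave 257 higher and 3708 lower genes and moved the median log2 fold change of all genes from -0.12 to -0.96. The 3 libraries of Roquin IP lay above all of control IP for 1027 genes and below for 765. For unpaired libraries chance gives 10% of genes in both directions together, and the share under the pairing by number was not worked out.

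Nfkbid reached 50580 ± 11340 CPM (TMM-scaled, as are all levels here) in Roquin IP (SD, n = 3), 107.8 ± 8.96 in control IP and 293.2 ± 372.5 in the input, and its log2 fold change over control IP was 8.87 (SE 1.00, edgeR adjusted p = 4.42e-05). Tnf had a log2 fold change of 7.57 (SE 0.63, adjusted p = 2.97e-06), and its level rose from 1714 ± 649.2 CPM in control IP to 324900 ± 114400 in Roquin IP. Irf4 was at 372.1 ± 102.7 CPM against 2.12 ± 1.71 (log2 7.25, adjusted p = 3.78e-06), Socs1 at 178.5 ± 113.3 against 1.17 ± 1.10 (6.95, 2.25e-05), and Ccl4 at 152200 ± 84080 against 1495 ± 565.4 (6.67, 8.57e-06). Rc3h1 was at 29050 ± 5261 CPM against 294.2 ± 74.8 (log2 6.63, SE 0.43, adjusted p = 6.86e-07), and Rc3h2 at 5037 ± 1192 against 115.4 ± 10.0 (5.45, SE 0.34, adjusted p = 6.86e-07). Tcf7l2, a transcription factor of the Wnt pathway, had a log2 fold change of 6.28, Csf3, the granulocyte growth factor, 6.15, Id1, an inhibitor of helix-loop-helix transcription factors, 6.09, and Slc39a14, a zinc transporter, 6.02, with adjusted p from 6.86e-07 to 2.88e-05. Actb and Gapdh, cytoskeletal and glycolytic reference genes, did not pass, at -0.52 (adjusted p = 0.723) and -0.61 (0.639). With library size alone, Gapdh was called lower (-1.46, adjusted p = 0.0158). Lars2 differed by -0.12 (0.938).

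**Figure D1:**
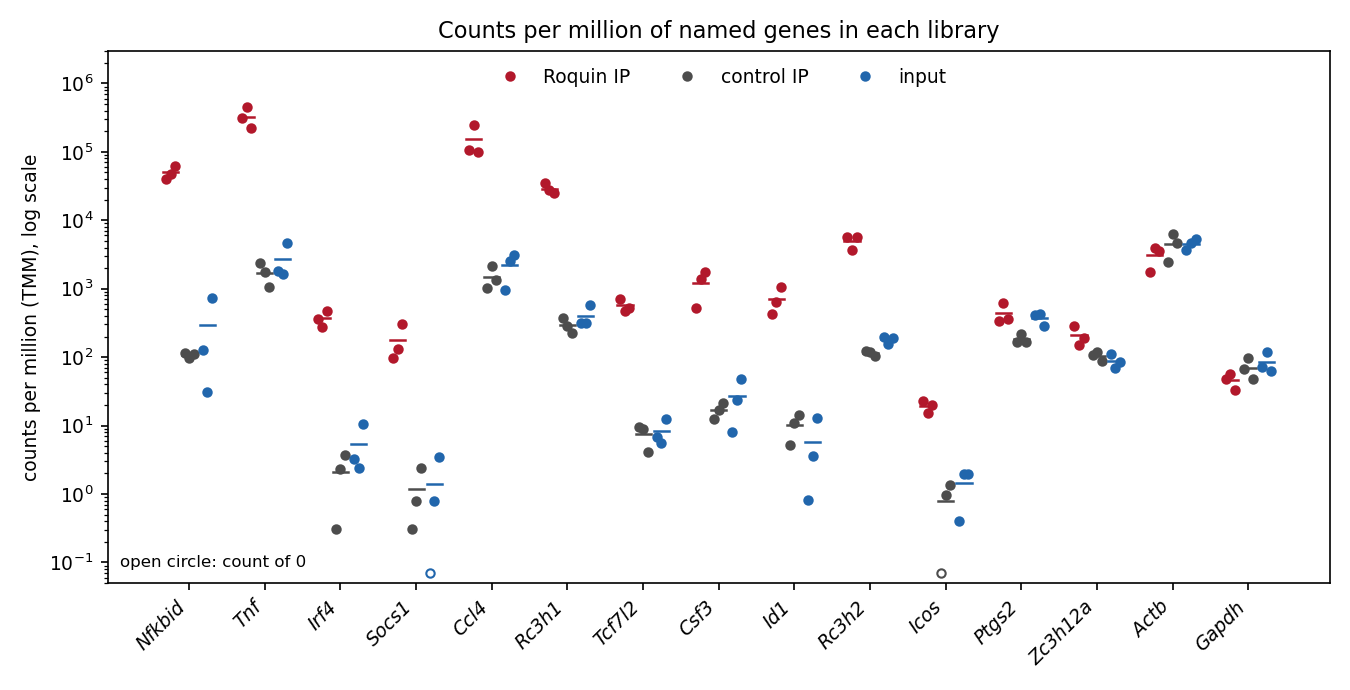
Levels in CPM (TMM-scaled, log axis) of 15 genes in the 9 libraries, with points for libraries, bars for group means and open circles at the bottom for a count of 0. Nfkbid averaged 50580 CPM in Roquin IP and 107.8 in control IP, while Actb and Gapdh did not pass between these groups with TMM scaling.

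The authors' deposited table gave the same comparison as a linear ratio with a p-value. It listed 249 genes with p under 0.05, all with a ratio over 1. Of these, 247 were tested here and 243 were also called higher, and 117 of the 360 genes called here were not past that threshold in the deposited table. The deposited ratio of Tnf was 191.8, of Irf4 179.2, of Socs1 155.8, of Ccl4 103.7 and of Rc3h1 99.8. Klf10, an early transcription factor, had a deposited ratio of 39.4 and lay just outside that threshold (0.0548), while edgeR gave a log2 fold change of 5.22 and an adjusted p of 2.66e-05.

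The comparison with the input asked which mRNAs were enriched relative to the lysate. Nfkbid, Tnf, Socs1 and Id1 were again among the highest. Socs1 had a log2 fold change of 7.07 and Id1 of 7.00, which were 8.73 and 8.32 without Input 3. For Socs1 these folds put the input near or under the floor of 3 counts (1.19 to 1.49 CPM per input library), so their size is uncertain. Among the lowest genes were Upf3b, a factor of nonsense-mediated decay, Esf1, a nucleolar factor of ribosomal RNA processing, Crnkl1, a splicing factor, and Snapc5, a subunit of the complex that transcribes small nuclear RNAs.

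Roquin IP held 521 genes at a higher and 267 at a lower level than the input, 513 and 248 of them by at least 2-fold. The fit with the replicate block called 956 higher and 769 lower, DESeq2 708 and 519, and library size alone 259 and 2668, with a median log2 fold change of all genes of -0.76 against -0.01. Leaving out 1 library moved both counts: the genes higher fell to 299 without Roquin IP 1, 329 without Roquin IP 3 and 298 without Input 2. The genes lower fell to 30 without Roquin IP 1, 99 without Roquin IP 2, 62 without Roquin IP 3, 138 without Input 1 and 86 without Input 2. Nfkbid had a log2 fold change of 7.43 (adjusted p = 0.000132) and Tnf of 6.92 (adjusted p = 5.83e-06). Input 3 held more of both than the other inputs, and without it they were at 9.31 and 7.56 (4.06e-05 and 4.08e-05). Upf3b was at 4.34 CPM in Roquin IP, 6.53 in control IP and 24.3 in the input (log2 fold change over input -2.44, SE 0.46, adjusted p = 0.00461), and Esf1 at 37.6, 39.7 and 181.6 CPM (-2.27, SE 0.34, adjusted p = 0.000698). Snapc5 (-2.28, adjusted p = 0.00801) and Crnkl1 (-1.99, 0.00181) were also lower. Tigd3, a transposase-derived gene, had 553 counts in Roquin IP and 0 in the input, at least 62.6-fold higher with the floor of 3 counts over the group, and its call over input ended without Input 2 (adjusted p = 0.0553). Over control IP, Tigd3 had a log2 fold change of 2.85 (SE 0.96) and did not pass (adjusted p = 0.209). It passed with the replicate block (3.67, adjusted p = 0.0384) and without control IP 1 (4.99, 0.00242), the library that held 33 of the 47 control counts.

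Both comparisons together picked 307 genes that were at least 2-fold higher over control IP and over input, 85.3% of the 360. Nfkbid, Tnf, Socs1, Irf4, Ccl4, Rc3h1, Tcf7l2 and Id1 were among them. These 307 genes took 48.7% ± 6.01 of the reads in Roquin IP (SD, n = 3), against 2.63% ± 0.0923 in control IP and 2.88% ± 0.210 in the input. They were chosen for being higher in these same libraries, so the direction of this contrast was given by the choice. Much of the share came from Tnf (mean 21.9% in Roquin IP) and Ccl4 (7.15%, 15.2% and 8.10% in Roquin IP 1, 2 and 3). Independent calls would share 19.3 genes, and simulated data without any effect, which keep the shared Roquin IP libraries, gave at most 0 in 20 datasets. Such data hold almost no adjusted calls to share, so the 0 says little, and they had no pairing by number. At an unadjusted p under 0.05, 508 genes passed in both, against a simulated mean of 34.4. The covariance across genes of the changes was 0.438 against 0.112 in the simulations, and r was 0.626 against 0.483. The fit with the replicate block gave 373 such genes, 306 of them shared. With library size alone the count was 198. The shared Roquin IP libraries were too few to divide into independent sets.

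**Figure D2:**
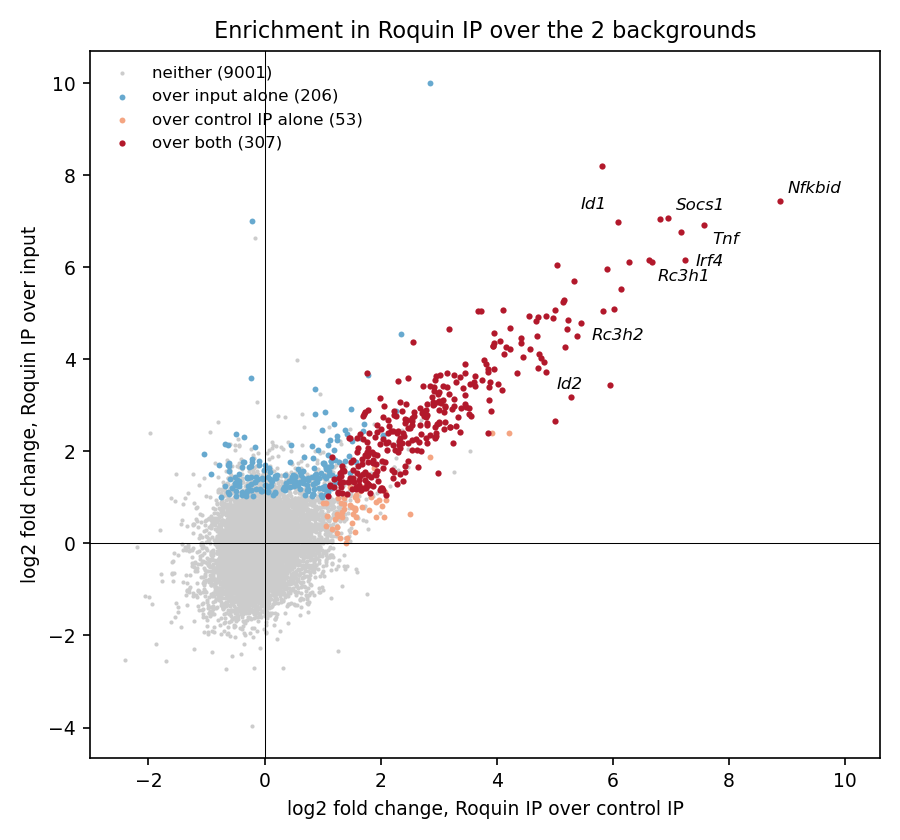
Log2 fold change of Roquin IP over control IP (x axis) against that over input (y axis) for 9567 genes, with the 307 genes at least 2-fold higher over both in dark red. Nfkbid lies farthest right, at 8.87, and 206 genes passed over the input alone.

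The comparison of control IP with the input measured what the beads alone retained. Tmem160, a mitochondrial protein gene, and Gemin7, which encodes a subunit of the complex that assembles splicing particles, were higher on the beads. Clk1, a kinase of splicing factors, Esf1, Hmgn5, a nucleosome-binding protein gene, and Samd9l, an interferon-induced antiviral gene, were lower. Clk1 was higher in Roquin IP over control IP (log2 fold change 5.00, adjusted p = 9.07e-06) and over the input (2.66, 0.00109).

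Control IP differed from the input at 78 genes higher and 29 lower, all by at least 2-fold. DESeq2 called 385 and 373, the fit with the replicate block 636 and 553, library size alone 57 and 10, and 1036 and 912 passed at an unadjusted p under 0.05. The edgeR calls changed on leaving out 1 library, which also leaves fewer libraries to test: 0 and 0 genes were called without Input 1 and without Input 2, 2 and 1 without control IP 2, 20 and 5 without control IP 3, 30 and 32 without Input 3, and 185 and 86 without control IP 1. With only the 6 libraries compared in the fit, 2 genes were higher and 1 lower. Tmem160 was at 31.4 ± 6.75 CPM in control IP and 3.94 ± 0.833 in the input (log2 fold change 2.98, SE 0.40, adjusted p = 0.0166). Its fold change stayed at 3.09 without Input 1 and 3.06 without Input 2, while the adjusted p rose to 0.0736 and 0.0900. Gemin7 (2.84), Ppm1m, a protein phosphatase gene (2.50), and Slc25a33, a mitochondrial pyrimidine carrier gene (2.49), were also higher. Ppap2c, a lipid phosphatase gene, was just past the threshold (2.87, adjusted p = 0.0481). Its call ended with RLE factors (0.0507), without Lars2 (0.0505), after thinning (0.0512), and without control IP 2 (0.141), control IP 3 (0.0667), Input 1 (0.0736), Input 2 (0.108) or Input 3 (0.0754). With only the 6 libraries compared, or without control IP 2, Tmem160 alone of the genes named here stayed called. Clk1 (-2.35), Esf1 (-2.19, with -2.15 without Input 1 and -1.88 without Input 2), Hmgn5 (-1.97), Samd9l (-1.94) and the splicing factor gene Cwf19l2 (-1.86) were the lowest named genes, and 1 predicted locus ranked lower still. Of the 78 genes higher on the beads, 54 were also higher in Roquin IP over the input. Of the 29 lower genes, 23 were also lower in Roquin IP over the input. Both comparisons share the input libraries. Data simulated without any effect, which keep them shared, gave at most 0 and 0 such genes in 20 datasets. Such data hold almost no adjusted calls to share, so this says little, and they had no pairing by number. At an unadjusted p under 0.05 the overlap was 510 higher and 540 lower genes, against at most 85 and 44 in the simulations. The covariance of the changes was 0.394 against a simulated mean of 0.129, and r was 0.585 against 0.535 (at most 0.556).

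Reported Roquin targets were examined next. Nfkbiz, an inducible regulator of NF-kappaB, Ier3, an early survival gene, Icos, a costimulatory receptor gene best known from T cells, Ppp1r10, a phosphatase regulator, and Hmgxb3, a chromatin protein gene, were enriched besides Nfkbid, Tnf and Irf4. Of 17 listed targets 12 were measured, and 10 of them were higher in Roquin IP over control IP (11 adjusted over the list alone, 11 with the replicate block), with a median log2 fold change of 4.10. Several members were reported in the study these samples belong to, so the list is not independent of them. The camera test passed (adjusted p = 5.11e-22) and held with an estimated correlation (p = 0.00472). Over the input 10 were higher, with Zc3h12a and Pim3 in the place of Rel and Ptgs2 (11 adjusted over the list alone, 11 with the replicate block, median 3.75, adjusted p = 4.21e-13, estimated-correlation p = 0.0196).

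Among these targets, Nfkbiz had a log2 fold change over control IP of 5.01 (SE 0.37, adjusted p = 1.08e-06), Ier3 of 4.56 (3.77e-05), Icos of 4.35 (0.00109), Ppp1r10 of 3.85 (4.63e-05) and Hmgxb3 of 3.07 (2.22e-05). The 3' end of Hmgxb3 overlaps Csf1r on the other strand, which leaves its counts uncertain. Rel, an NF-kappaB subunit gene, was higher by 1.55 (SE 0.30, adjusted p = 0.00601) but not with library size alone (0.0810), and over the input by 0.76 (0.147, or 0.0248 with the replicate block). Ptgs2, which encodes the prostaglandin synthase COX2, was higher by 1.25 (SE 0.31, adjusted p = 0.0315). Its call ended with library size alone (0.316) and without Roquin IP 2 (0.222), control IP 1 (0.0940), control IP 2 (0.0660) or control IP 3 (0.122), and over the input it did not pass (0.22, adjusted p = 0.714). Zc3h12a, the gene of the decay endonuclease Regnase-1, did not pass over control IP (1.00, adjusted p = 0.114) except with the replicate block (0.0235) and DESeq2 (0.0299). Over the input it was higher (1.22, adjusted p = 0.0245), but not without Roquin IP 1 (0.138), Roquin IP 3 (0.0594), Input 2 (0.103) or Input 3 (0.0714) or with library size alone (0.271). Pim3, a kinase gene, did not pass over control IP either (-0.17, adjusted p = 0.918). Its call over the input (1.33, adjusted p = 0.0461) ended without Roquin IP 1 (0.0845), Roquin IP 2 (0.0568), Roquin IP 3 (0.214), Input 1 (0.145) or Input 2 (0.167) and with library size alone (0.263), and it did not pass in control IP against the input (0.0617) except with the replicate block (1.48, 0.00202), DESeq2 (0.00768), no filter (0.00111) or without control IP 1 (1.71, 0.0414). Tnfrsf4, the gene of the costimulatory receptor OX40, lay under the count filter with 77 counts in Roquin IP and 0 in control IP, at least 24.9-fold higher with the floor of 3 counts over the group. Against 1 count in the input its ratio was 26.1 (counting interval 4.55 to 1050). Il6 and Cxcr3, genes of a cytokine and a chemokine receptor, had 76 and 53 counts over all libraries, and Ctla4 and Ifng had 0.

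Other lists fixed beforehand held a few strongly enriched members among many that did not pass. Of 21 measured cytokines and chemokines, 3 were higher (4 adjusted over the list alone): Tnf, Ccl4 and Csf3. The list had a median log2 fold change of 0.37 and a mean of 1.29 and passed camera (adjusted p = 0.000454, estimated-correlation p = 0.357). Ccl2, a monocyte chemokine gene, did not pass (2.69, adjusted p = 0.14) but did with the replicate block (0.0336) and without control IP 3 (0.0417). Of 28 genes of the NF-kappaB pathway, Nfkbid, Nfkbiz and Rel were higher (6 adjusted over the list alone, 6 with the replicate block). The list did not pass camera (adjusted p = 0.291), with a median of -0.14, a mean of 0.50 and an upward test, but passed fry upward (adjusted p = 0.0486). Tnfaip3, a deubiquitinase gene that restrains NF-kappaB, was at 1.16 (adjusted p = 0.0627) and passed with the replicate block (0.00125) and without control IP 1 (0.0212). Immediate early genes passed upward with 6 of 38 higher (7 adjusted over the list alone, and 8 higher and 1 lower with the replicate block), Klf10, Id2 and Ier3 among them, while the median was -0.11 and the mean 0.58 (adjusted p = 0.0363, estimated-correlation p = 0.328, and 0.0579 with the replicate block, or 0.00808 after a correction for GC content and transcript length in that fit). MAP kinase feedback genes also passed (adjusted p = 0.0363, estimated-correlation p = 0.307), with 4 of 17 higher (4 adjusted over the list alone), a median of -0.0021 and a mean of 0.81. Map3k8, the gene of the kinase TPL2, was higher by 4.76 (adjusted p = 6.86e-07). Spred1, an inhibitor of RAS signalling, was higher by 1.67 (0.00877) but not without Roquin IP 1 (0.0548), without control IP 2 (0.0520) or with library size alone (0.0634). The phosphatase gene Dusp6 was higher by 2.45 (0.0425), and its call ended without any 1 of the 6 libraries compared (0.0515 to 0.194).

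The mRNA decay machinery passed upward (adjusted p = 0.00125, estimated-correlation p = 0.328). Besides Rc3h1 and Rc3h2, Cnot2 (1.95, adjusted p = 0.000652) and Cnot7 (1.93, 0.000267), subunits of the CCR4-NOT deadenylase, were among the 6 of 41 members that were higher (9 adjusted over the list alone, 8 with the replicate block, median 0.17). Lysosomal genes had a median of 0.44 with 2 of 27 higher (2 adjusted over the list alone; camera adjusted p = 0.00125, estimated-correlation p = 0.357). The cholesterol transporter gene Npc1 was higher by 1.73 (adjusted p = 0.0143), and its call ended without Roquin IP 1 (0.105) or control IP 3 (0.0534) and with library size alone (0.0865). ER folding genes passed upward with 0 of 23 called by edgeR (0 adjusted over the list alone, 0 by DESeq2, 1 higher with the replicate block, 1 higher and 1 lower at an unadjusted p under 0.05), a median of 0.38, an adjusted p of 0.0202 and an estimated-correlation p of 0.507, but not with library size alone (0.0939). Macrophage identity genes (median 0.37, adjusted p = 0.135) and interferon response genes (-0.11, 0.422) did not pass, with 0 of 21 and 0 of 28 called by edgeR, adjusted over the list alone, with the replicate block or by DESeq2, and 3 and 0 at an unadjusted p under 0.05.

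Lists that passed downward had small changes spread over many members, and camera passed them only at the preset correlation. Nuclear-encoded oxidative phosphorylation genes had a median log2 fold change of -0.38 (adjusted p = 3.43e-05, estimated-correlation p = 0.357, 74 genes). Replication histones were at -0.39 (adjusted p = 0.00109, estimated-correlation p = 0.518, 67 genes), and ribosomal proteins at -0.24 (0.00335, estimated-correlation p = 0.507, 82 genes). edgeR called 0 members of the first and 0 of the second list, also adjusted over the list alone, while 7 and 3 were lower at an unadjusted p under 0.05. DESeq2 called 1 and 0 lower, and the fit with the replicate block 2 and 1. Hist1h4m, a histone gene, was at -0.86 (adjusted p = 0.268, or 0.0399 with the replicate block). After a correction for GC content and transcript length, in the fit with the block, the histones and the ribosomal proteins no longer passed (0.271 and 0.573), while macrophage identity genes passed upward (0.0232, from 0.0563 before it). Cell cycle genes (median -0.34, adjusted p = 0.0141, estimated-correlation p = 0.357), housekeeping genes (-0.44, 0.0301, estimated-correlation p = 0.41) and translation factors (-0.29, 0.0363, estimated-correlation p = 0.307) also passed. No housekeeping gene was called by edgeR or adjusted over the list alone (0), with 1 higher and 2 lower at an unadjusted p under 0.05, 1 lower by DESeq2, and 1 higher and 1 lower with the replicate block. The cell cycle, ribosomal protein and translation lists held 1 called gene each (1 adjusted over the list alone; 2, 1 and 2 with the block): Cenpf, a kinetochore gene, higher by 3.90 (adjusted p = 1.88e-05), Rpl22l1, a ribosomal protein paralog gene, by 4.70 (3.6e-05), and Eif4a1, a translation initiation helicase gene, by 1.27 (0.00856). The Eif4a1 call ended without control IP 2 (0.0683) and with library size alone (0.228). In all, 13 of 16 lists passed, and 1 with an estimated correlation. The fry test, which asks whether members move 1 way and not whether they differ from other genes, passed 7 lists: targets, cytokines, NF-kappaB, immediate early, MAP kinase feedback and decay machinery upward, and translation factors downward. Lck, from the lymphocyte markers (-1.01, adjusted p = 0.771), and Acta2, from the fibroblast markers (-0.01), were the only measured members of those lists, and none of the mitochondrially encoded or nuclear noncoding RNAs was in the table.

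Against the input, 7 of 16 lists passed, 5 of them with an estimated correlation. With fry 8 passed, but not the ribosomal proteins (0.174). Among the 8 were the NF-kappaB (adjusted p = 0.0254) and decay machinery lists (0.00959), which camera did not pass (0.335 and 0.0808). The decay machinery list passed camera with the stricter filter (adjusted p = 0.0466). The immediate early list passed upward, with 11 of 38 members called higher (12 adjusted over the list alone, 16 with the replicate block), a median log2 fold change of 0.55 and an adjusted p of 4.47e-05 (estimated-correlation p = 0.0304). MAP kinase feedback genes had the same median, with 4 of 17 called (6 adjusted over the list alone, 7 with the replicate block; list adjusted p = 0.000162, estimated-correlation p = 0.0304). The interferon response list passed downward (median -0.52, adjusted p = 0.00345, estimated-correlation p = 0.0374), but only 2 of 28 members were called lower (2 adjusted over the list alone, 5 with the replicate block). The translation factor list also passed downward (-0.35, 0.00112, estimated-correlation p = 0.0304), with 6 of 28 members called lower (9 adjusted over the list alone, 11 with the block) and 1 higher. The cell cycle (-0.57, 0.000362) and ribosomal protein lists (-0.59, 2.39e-06) passed camera downward only at the preset correlation (estimated-correlation p = 0.217 and 0.607). Of these, the cell cycle list also passed fry downward (adjusted p = 0.0254). These lists held 7 and 10 genes called lower (8 and 11 adjusted over the list alone, and 11 and 19 with the block), and 2 and 1 called higher. Cytokines and chemokines did not pass (0.197) except with library size alone (0.0212). In control IP against the input 4 lists passed camera upward and 4 downward, and 0 with an estimated correlation. The fry test passed 4 lists: immediate early and MAP kinase feedback upward, and interferon response and translation factors downward. Camera did not pass the translation factors there (adjusted p = 0.0573). Macrophage identity genes had the lowest median there (-0.60, adjusted p = 0.0194, estimated-correlation p = 0.474), with 0 genes called lower by edgeR, 9 adjusted over the list alone, 8 with the replicate block, 6 by DESeq2 and 9 at an unadjusted p under 0.05. The immediate early list passed upward (median 0.46, adjusted p = 0.0194, estimated-correlation p = 0.21), with 1 of 38 members called higher (4 adjusted over the list alone, 7 with the block). MAP kinase feedback genes passed upward too (0.43, adjusted p = 0.0401, estimated-correlation p = 0.21), though not with the stricter filter (0.168), with 0 of 17 called higher by edgeR, 1 adjusted over the list alone, 3 with the block, 1 by DESeq2 and 3 at an unadjusted p under 0.05. The interferon response list passed downward (-0.40, adjusted p = 0.0334, estimated-correlation p = 0.21), with 0 of 28 called lower by edgeR, 3 adjusted over the list alone, 5 with the block, 3 by DESeq2 and 6 at an unadjusted p under 0.05. Cytokines and chemokines passed downward there only with the replicate block (0.0262) and the stricter filter (0.0463).

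The authors' classes of predicted CDEs were compared next. Nfkbid, Tnf, Nfkbiz, Rc3h1, Rc3h2, Ier3, Icos, Ppp1r10 and Bmpr1a, a receptor gene for bone morphogenetic proteins that was chosen after its value was seen, carried a conserved CDE in the 3' UTR per the deposited table and were higher in Roquin IP over control IP. Bmpr1a was 25.8-fold higher. Of 37 tested genes with such an element, 23 (62.2%, exact interval 44.8% to 77.5%) were at least 2-fold higher, and all 23 were also higher over the input. Genes without a predicted element were higher in 3.49% of 9437 cases, an odds ratio of 45.4 (22.2 to 96.5, Fisher's exact p = 2.41e-24, adjusted over 3 classes 7.23e-24). The class median log2 fold change was 2.48. Elements in the 3' UTR that were not conserved went with 4 of 38 genes higher (10.5%, odds ratio 3.26, Fisher's exact p = 0.0433, adjusted p = 0.0649), and elements in the coding frame with 4 of 55 (7.27%, odds ratio 2.17, exact p = 0.126). Among the 14 conserved-element genes that were not called were Edem3, an ER degradation gene (log2 1.25, adjusted p = 0.0646, or 0.0271 with the replicate block), and Atp2b1, a calcium pump gene (0.74), both chosen after their values were seen. Of the 360 genes higher in Roquin IP, 91.4% had no predicted element, with Irf4, Socs1, Ccl4, Tcf7l2, Csf3 and Id1 among them.

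**Figure D3:**
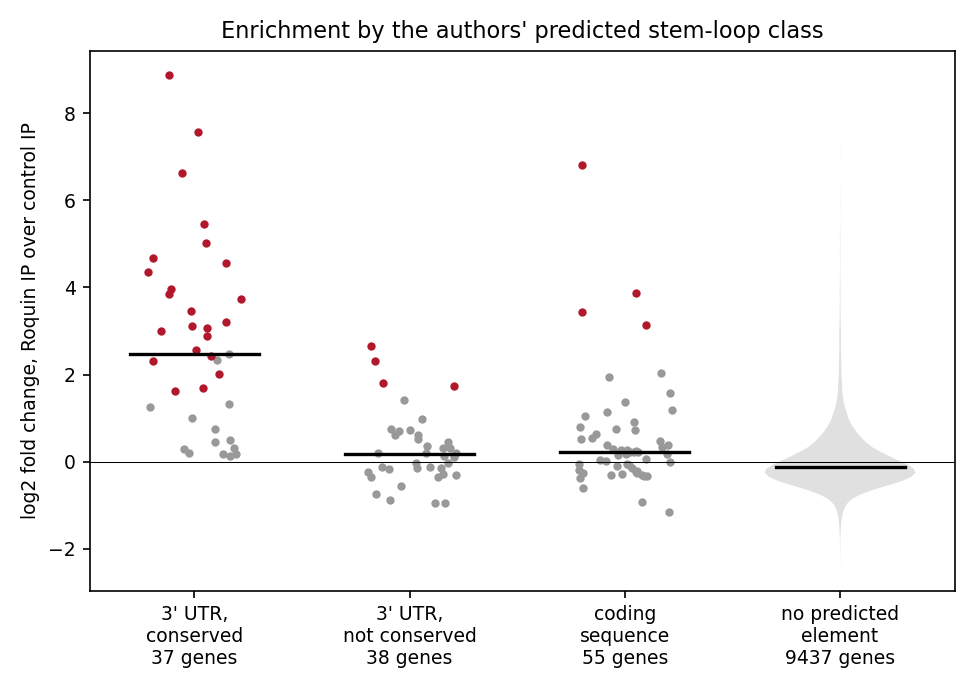
Log2 fold change of Roquin IP over control IP by the authors' predicted class, for 37 genes with a conserved 3' UTR element, 38 with one not conserved, 55 with one in the coding frame and 9437 with none, with black lines for medians and red points for called genes. The medians were 2.48, 0.17, 0.22 and -0.12.

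A search of 3' UTRs with the CDE pattern placed these stem-loops on the genome. The Tnf element, TTCTGTGAA in TGTTTTCTGTGAAAACG, lay in the 3' UTR in exon 4 on chromosome 17 at 35199588 to 35199596 (GRCm38, minus strand). Nfkbid held 2 copies in exon 12 on chromosome 7, at 30428405 to 30428413 and 30428433 to 30428441. Nfkbiz held 1 in exon 12 on chromosome 16 at 55812617, Rc3h2 1 in exon 22 on chromosome 2 at 37373812, and Rc3h1 2 in exon 20 on chromosome 1 at 160968042 and 160971663. The stem sequence TAACTTCTGTGAAGTTG stood in both Rc3h1 and Rc3h2.

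Of 567 genes with TTCYRYGAA in the 3' UTR, 62 (10.9%) were higher in Roquin IP over control IP, against 3.35% of 8873 genes without it (odds ratio 3.54, 2.61 to 4.75; Fisher's exact p = 1.68e-14, adjusted over 12 tests 6.72e-14). With UTR length and the mean level over all libraries as covariates the odds ratio was 2.08 (1.51 to 2.86). That level includes Roquin IP, and with the level in the input alone it was 2.30 (1.70 to 3.10). With the strict stem, 34 of 132 genes (25.8%) were higher (odds ratio 9.58, 6.19 to 14.5, exact p = 1.57e-19; with covariates 5.86, 3.69 to 9.31, and with the input level 6.78, 4.46 to 10.3). Matches without the strict stem had an odds ratio of 1.17 with covariates (0.764 to 1.79), or 1.22 with the input level (0.805 to 1.83). Before covariates a swapped stem had an odds ratio of 1.77 (1.18 to 2.58, adjusted p = 0.0096) and AU-rich elements of 1.85 (1.45 to 2.35, adjusted p = 2.19e-06), while a swapped loop did not pass (1.59, 0.994 to 2.45, adjusted p = 0.0536). With covariates the swapped loop, swapped stem and AU-rich elements were at 0.856, 0.921 and 1.17 (0.902 to 1.51), and with the input level the first 2 were at 0.937 and 1.01, with an interval of 0.936 to 1.54 for AU-rich elements. With the strict stem the swapped loop had 1.01 (0.203 to 3.1) and the swapped stem 0.881 (0.177 to 2.68) before covariates. In coding sequences TTCYRYGAA had an odds ratio of 1.27 (0.805 to 1.94, exact p = 0.242), and with the strict stem of 2.25 (0.936 to 4.68, exact p = 0.0556). Genes higher in Roquin IP had a median 3' UTR length of 2008 bases, against 1173 in the other genes, and a median UTR GC content of 41.1% against 44.4%.

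**Figure D4:**
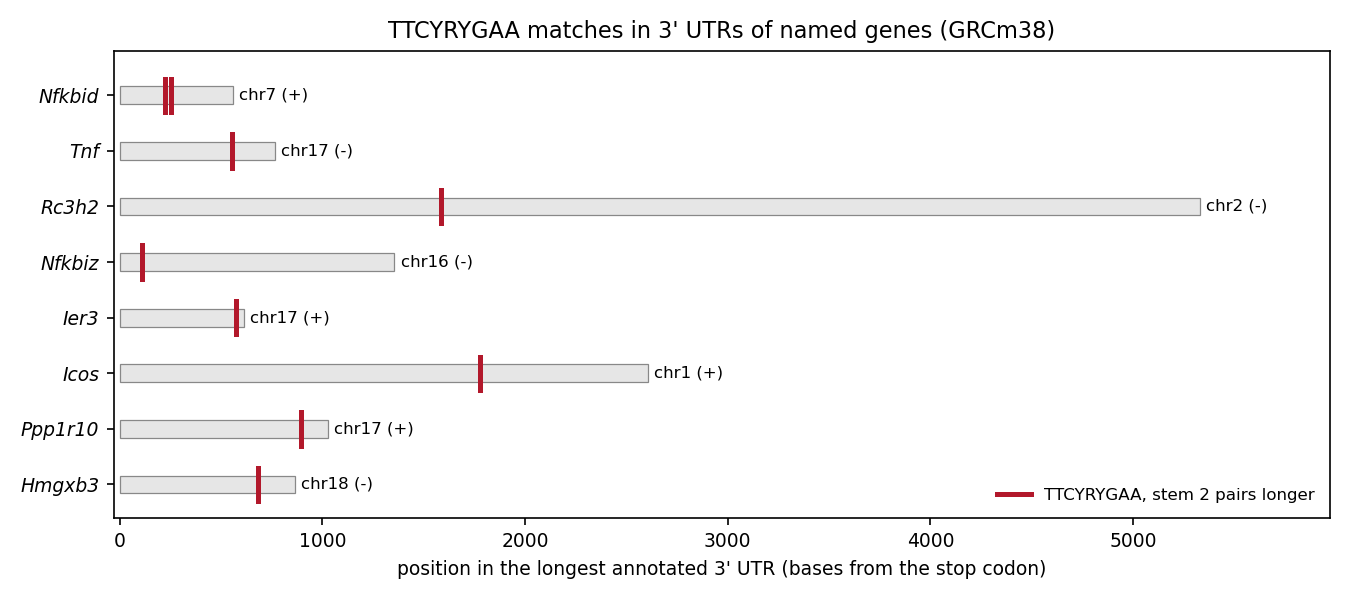
Position of TTCYRYGAA matches (red where the stem is 2 pairs longer) along the longest annotated 3' UTR, in bases from the stop codon, of Nfkbid, Tnf, Rc3h2, Nfkbiz, Ier3, Icos, Ppp1r10 and Hmgxb3. The Tnf match begins at base 549 of 764, and Nfkbid has 2 matches.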

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

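Leaving out Lars2, thinning to the smallest library, leaving out the 3 libraries numbered 1, the calls of other tests and the extra covariates for the stem-loops were chosen after the data were seen. Of the values for named genes under all alternatives, 2359 kept their side of the threshold, 116 lost and 64 gained a call. A turn in direction was counted only with a call, and 0 of the values turned so. Uncalled values among the 2359 could change direction, as for Pim3 over control IP (log2 fold change -0.998 to 0.219). Of the values for single lists 210 kept their call, 26 lost it and 4 gained it. The 360 genes higher in Roquin IP over control IP ranged from 257 with library size alone to 528 with the replicate block, and from 276 to 371 on leaving out 1 library. The pseudocount alternative was not run because the values are counts.

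Genes lower in Roquin IP than in control IP, 0 in edgeR, were 5 with DESeq2, 3708 with library size alone, 21 without a filter and 11 with the replicate block, and 0 to 3 on leaving out 1 library. Over the input, library size alone gave 259 higher and 2668 lower, the replicate block 956 and 769, DESeq2 519 lower and no filter 416 lower. Leaving out 1 library gave 298 (without Input 2) to 409 higher and 30 (without Roquin IP 1) to 192 lower, and leaving out the libraries numbered 1 gave 118 lower. In control IP against input, DESeq2 gave 385 higher and 373 lower, no filter 335 and 229, the stricter filter 130 and 70, the replicate block 636 and 553, and only the groups compared 2 and 1. Library size alone gave 10 lower. Leaving out 1 library gave 0 (without Input 1 or Input 2) to 185 higher and 0 to 86 lower (the highest without control IP 1), and without the libraries numbered 1 the counts were 0 and 0. Genes enriched over both backgrounds were 198 with library size alone and 221 to 316 on leaving out 1 library. With an estimated correlation 1 list passed in Roquin IP against control IP and 0 in control IP against input. The stem-loop odds ratio was 1.27 in coding sequences. Library size alone leaves the high share of Tnf and other enriched reads in the totals, which lowers the scaled level of the other genes in Roquin IP. For the other alternatives the cause was not tested.

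Depth limits the genes with few reads: the input libraries held 1799390 to 2122288 reads, and Tnfrsf4, Il6 and Cxcr3 lay under the filter. Thinning every library to 1799390 reads left 321 genes higher in Roquin IP over control IP.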

Other observations

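The tests of UTR length, of carry-over, of a culture effect and of depth were chosen only after the result was seen, as were the follow-ups of the triloop test, the gene families, the corrected list tests, the groupings by number and the level in the input as a covariate. Irf4, Socs1, Ccl4, Csf3, Id1 and Tcf7l2, which were 68.3- to 152-fold higher in Roquin IP than in control IP, had no TTCYRYGAA match in the 3' UTR, and only 62 of the genes higher in Roquin IP had one. A hypothesis fixed before its result was that other stem-loops with a pyrimidine-purine-pyrimidine (YRY) triloop on a stem of 6 pairs mark such genes. Among genes without the match, a YRY stem-loop had an odds ratio of 2.95 (2.26 to 3.87) with UTR length and level as covariates. With the level in the input alone it was 3.01 (2.32 to 3.90). In the first model YRY was the highest of 8 triloop classes, where the others had 1.1 to 1.53. The YRR, RYY and RRY classes also passed (1.53, 1.48 and 1.47, logistic regression, adjusted p = 0.00752, 0.0088 and 0.0088). A YRY stem-loop was present in 57.6% of the higher genes without the match and in 24.3% of the other genes without it. The share of genes higher was 1.9% with no such stem, 6.14% with 1, 11.8% with 2 and 12.9% with 3 or more, though UTRs with more stems were also longer. With all 8 classes and GC content in 1 model the YRY odds ratio was 2.77 (2.1 to 3.64), and for genes higher on beads over the input it was 0.556 (0.282 to 1.1). These values are in line with Roquin binding a wider class of YRY stem-loops, and may be tested by mutating single stems.

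Candidate stems lay in the 3' UTRs of Irf4 (GGGGTATATTATCCC, chromosome 13 at 30765359 to 30765373, GRCm38), Socs1 (TTCTGCTGTGCAGAA, chromosome 16 at 10783883 to 10783897) and Ccl4 (GTCTCCCATGGAGAT, chromosome 11 at 83664580 to 83664594). Long 3' UTRs without any particular motif could also raise recovery: among genes without the match the odds ratio was 3.31 (2.45 to 4.47) per 10-fold UTR length, with coding length, GC content and level as covariates, and 3.82 (2.84 to 5.15) with the input level. These calls were over control IP alone. Across genes, Spearman's rho with transcript length was 0.259 for the change over control IP and 0.0175 over the input. For control IP over the input it was -0.179. The YRY odds ratio had UTR length as a covariate, but the length test did not have the stems as one. With both in 1 model and the input level, length had 2.29 (1.66 to 3.16) and YRY stems 2.77 (2.14 to 3.61), so both explanations stay open together. Slc39a14, Klf10, Rpl22l1 and Cenpf had no YRY stem of this form.

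Some further genes were picked after their values were seen, and no list of their pathway was tested. Id1, Id2 and Id3, inhibitors of helix-loop-helix factors, had log2 fold changes over control IP of 6.09, 4.85 and 5.33, and the receptor genes Bmpr1a and Bmpr2 of 4.69 and 2.08 (adjusted p = 0.0196 in edgeR for Bmpr2, which did not pass over the input, 0.167). Socs1, Socs4 and Socs7 were 3 of 6 tested Socs genes (Fisher's exact p = 0.000971), while Socs3 was at -0.01. Adjusted over 313 families sharing a name stem, no family passed (0.304 for Socs).

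Lars2 held 28.6% to 41.5% of the reads in the control IP libraries and 37.5% ± 4.49 (SD, n = 3) in the input. A rise of mitochondrial synthetase genes in general is argued against, because Lars2 lay at least 30100 times above the median of 16 other such genes in each input library. Reads of ribosomal RNA assigned to Lars2 stay a candidate explanation: 0 bases aligned with 360 annotated ribosomal RNAs, but the longest nuclear one held 1849 bases and no full-length large-subunit RNA was among them. That outcome would have met the bound first written against this explanation, which was wrong because the sequence it needs was not there to align. No other biological explanation was tested.

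Input 3 held more Nfkbid (9 times the mean of the other inputs) and Tnf (2.65 times). A culture with more of these mRNAs should also raise them in control IP 3, if libraries of 1 number share a culture. There Nfkbid and Tnf were at 1.04 and 0.509 times the other control IPs, which speaks against it for both genes. The bound for this test was first written for them alone and rewritten, after those values were seen, for a set of 17 strongly enriched genes. Over that set control IP 3 had a median of 0.94 times the other control IPs (quartiles 0.688 and 1.08). The set was chosen by its level in Roquin IP 3, and its median in Input 3 was only 1.35 times the other inputs. That is under the rise the bound asked for, so the set could not have met it and cannot decide. Carry-over of Roquin IP reads into Input 3 may explain the higher levels: the excess was 1.02% of the Roquin IP 3 level for Nfkbid and 1.3% for Tnf. Over 15 other genes its median was 0.558% with 11 positive and an upper quartile of 1.15%. Ccl4 was at 1.29%, Ier3 at 1.24% and Rc3h1 at 1.06%, while Nfkbiz was at -0.187% and Hipk1 at -2.47%, so carry-over stays open.

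Between control IP and input, the change followed GC content (Spearman rho 0.44 across genes, which are not independent) and transcript length (-0.179). Thinning all libraries to 1799390 reads kept 100% of the median log2 fold change of the called genes in the fit with the block, and 850 of 1189 calls. Thinning keeps the expected share of each gene in a library, so this outcome cannot decide for or against depth. GC content and length may account for part of it: a correction for both kept 78.9% (1.09 to 0.86) with the block, and 574 of 1189 calls, and 79.2% without it. Lists passing with the block went from 9 to 5 after it, 4 of them shared. In Roquin IP against control IP the correction kept 92.4% of the change and 311 of 360 calls, while genes lower went from 0 to 5, or from 11 to 112 with the block. A difference in what the beads retain stays open.

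With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. In Roquin IP against control IP the real split gave 360 genes and 13 lists, and the highest others 0 and 8. In Roquin IP against input these were 788 and 7, against 0 and 9, and 4 of the 10 splits gave as many lists. In control IP against input they were 107 and 8, against 0 and 7. Apart from those lists only the real split, 1 of 10, gave as many. The 4 splits that part all number pairs had highest others of 0 genes in each comparison and of 6, 7 and 5 lists, and the other 6 splits each keep 2 same-number pairs together. For the genes enriched over both backgrounds, of 100 groupings drawn from 840 only the real 1 gave as many (307), and the highest other gave 0. A count this large would thus be rare if libraries were assigned to groups at random. Groupings that mix Roquin IP with other libraries can widen the spread within groups, so they do not show how many of the 307 are chance calls. The draws did not take the numbers into account, so 100 of the 108 groupings with 1 library of each number per group were also drawn. Again only the real 1 gave as many, and the highest others gave 259 and 255 with the Roquin IP libraries still together and only the backgrounds exchanged, and 22 with the input libraries in their place.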
